A study of Mus musculus with 30 samples.

How the data were processed

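The data are the deposited gene counts of 30 RNA-seq libraries of mouse lung, 5 from each of 6 groups made by 2 genotypes (wild type and MEK2-deficient) and 3 time points (days 0, 2 and 4 of infection). Per the labels' protocols, total RNA was extracted with the NucleoSpin RNA midi kit, full-length cDNA was amplified, and libraries were made with the Nextera XT kit. The authors deposited whole-number counts per gene in a table of 53471 entries. The submitters' processing notes name FastQC 0.11.3, STAR 2.4.2a, Picard 1.134, HTSeq 0.4.1 and GRCm38. How each was used is not given in the sources used here, nor is a strand setting, so antisense and overlapping genes are uncertain. Near-identical copies (C1rb and C1s2, pseudogenes such as Ear-ps9 and Hmgb1-ps7, the Stfa, hemoglobin and Saa families) are uncertain too, since reads can be split between them.

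Each library's group was taken from its labels. Of the gene IDs 6 appeared in 2 entries with identical counts and were kept as 1 entry, leaving 53465 genes, of which 3433 had no symbol and 53360 had a position in GENCODE M21. Genes with no symbol held 0.0902% to 0.153% of counts and were tested but not named. Total counts were 2411418 to 4795852 per library. A total of 3 counts in 1 library is worth 0.626 to 1.24 CPM, and smaller values carry little information. No pair of libraries of a group differed by as little as counting noise.

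Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr by group (minimum count 10, minimum total 15), 1 robust quasi-likelihood fit of all 30 libraries with 6 groups, and glmQLFTest per comparison on 14544 genes. P-values were adjusted by Benjamini-Hochberg, and every adjusted p of a gene below is from this test, with 0.05 as the threshold. The comparisons were knockout against wild type at each day, each pair of days within a genotype, and the differences between genotypes in those changes. Log2 CPM for principal components and gene lists used a prior count of 2. A fold against a group with 0 counts is given as a lower bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Differences between responses are fitted values without such bounds, and where a gene had 0 to 3 counts in a group its counts are given. Intervals and floors cover counting error and no other.

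The text names genes from among those given by a rule set before the data were examined. For each comparison these are Map2k2, then the 8 largest rises and 8 largest falls (4 and 4 for day 4 against day 2 and for differences between responses) among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the 5 and 5 libraries, then up to 4 members of each list described, by smallest p. For differences between responses the overlap condition was not used. Predicted genes (Gm numbers, Rik), immunoglobulin and T cell receptor segments and sex-linked genes were left out of the largest changes. Not every gene that the rule gives is named in the text. A further gene among the largest differences in response is not reported here.

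A total of 38 lists were tested: signalling (ERK targets, the RAS-RAF-MEK-ERK pathway, immediate early genes), inflammation (cytokines, type I interferon, interferon-gamma, antimicrobial and inflammasome genes), cell types (neutrophil, immature neutrophil, monocyte, alveolar macrophage, alternative macrophage, MHC class II, T, NK, B, plasma, alveolar type 1 and 2, transitional alveolar, ciliated, club, endothelial), tissue state (matrix, metalloproteinases, resolution, cell cycle, hypoxia, coagulation, cholesterol, circadian) and other tissues (erythroid, cardiac, skeletal muscle, adipose, thymus, upper airway). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 38 lists of a comparison, with camera at the estimated correlation and fry beside it. A list's count is of genes past the threshold over all genes, and "adjusted over the list alone" is the count when p-values are adjusted within the list.

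The procedure was also tested on simulated data, with 50 genes at each of 4 fold sizes among 14544. The simulated spread was the fitted trend, without gene-specific spread, correlation between genes, libraries that stand apart or other group differences. The rates below need not hold for the real libraries. For knockout against wild type at day 0 it recovered 16%, 58%, 72% and 94% of changes of 1.5-, 2-, 4- and 8-fold, and called 0.0349% of 14344 unchanged genes. At day 4 it recovered 22%, 50%, 88% and 98%. For the difference in response from day 0 to day 4 it recovered 4%, 36%, 70% and 80%.

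Alternatives set before the data were examined were DESeq2 1.42.0 size factors in edgeR, no filter beyond 1 count (29950 genes), a stricter filter (14622 genes), the DESeq2 Wald test, limma voom with sample weights, a fit of the compared groups alone, the replicate number as a block, leaving out each library, glmTreat against a 1.5-fold change, and, for comparisons with day 4, leaving out X and Y genes. Leaving out 3 libraries that stand apart and thinning every library to 2411418 counts were chosen after seeing the data. The 3 libraries are wild-type library 3 of day 4 and knockout libraries 3 and 4 of day 0. An outlier rule over 17 quantities flagged the wild-type library and neither of these knockout libraries.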

Results

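Lung RNA was sequenced from wild-type mice and from mice deficient in MEK2, the kinase encoded by Map2k2 that phosphorylates the mitogen-activated kinases ERK1 and ERK2. Lungs were taken before infection (day 0) and at day 2 and day 4 after infection with Pseudomonas aeruginosa, a Gram-negative bacterium that causes pneumonia. The 2 genotypes and 3 times made 6 groups with 5 libraries in each, 30 libraries in all. Every animal of days 0 and 2 was female and every animal of day 4 was male according to the labels. The series asks what part MAP2K2 has in lung injury, and the comparisons were knockout against wild type at each day, each later day against an earlier one within a genotype, and the difference between the genotypes in those responses. Total counts per library lay between 2411418 and 4795852. The ranges were 2411418 to 4723714 (wild type) and 3248307 to 3998298 (knockout) at day 0. At day 2 they were 3051105 to 3602859 and 3127531 to 4058556, and at day 4 they were 3538493 to 4795852 and 2811266 to 3965999. In log2 changes below, the value after ± is a standard error worked back from the change and its quasi-likelihood F statistic. It is approximate, above all for genes with few counts. Each group has n = 5, and a positive value means higher in the knockout or at the later day.

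Map2k2 (ENSMUSG00000035027, chromosome 10, 81105915 to 81133975) was lower in every knockout library than in every wild-type library of the same day. In CPM (counts scaled to library size, mean ± SD, n = 5), wild-type lungs held 125 ± 11, 209 ± 28.5 and 182 ± 27.9 at days 0, 2 and 4, and knockout lungs held 34.3 ± 6.29, 85.6 ± 8.17 and 45.5 ± 7.19. The knockout level was 27.5%, 40.9% and 25.0% of the wild-type level. The log2 changes between genotypes were -1.86 ± 0.13, -1.29 ± 0.13 and -2 ± 0.13 (adjusted p = 2.45e-11, 6.91e-08 and 2.57e-12). Counts cover the whole gene, and which part of it is deleted is not given in the sources used here. Map2k2 also rose from day 0 to day 2 in both genotypes, by 0.75 ± 0.12 in wild type (adjusted p = 9.44e-06) and by 1.32 ± 0.13 in the knockout (adjusted p = 2.31e-09). Y-linked genes had 0 to 5 counts in the 20 libraries labelled female and 454 to 663 in the 10 labelled male. Xist, transcribed from the inactive X chromosome, had 0 to 22 counts in males and 56 or more in 19 of the female libraries. Knockout library 2 of day 0, labelled female, had 2 Xist counts and 0 Y-linked counts.

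**Figure D1:**
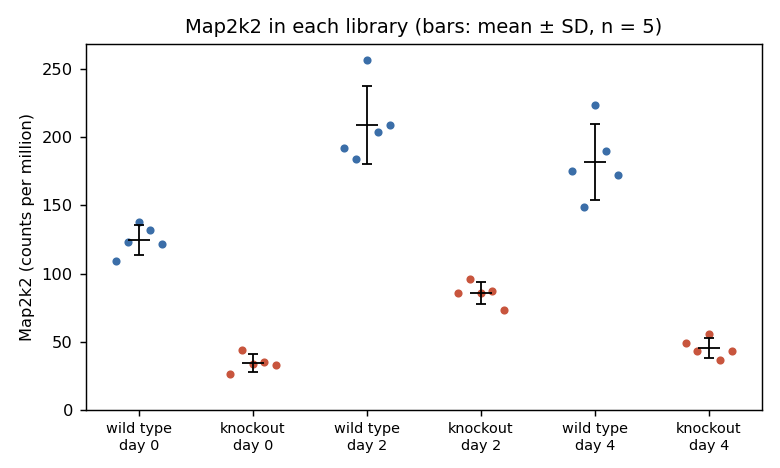
Map2k2 in CPM in each of the 30 libraries, by genotype and day, with the mean and SD of the 5 libraries of each group. The highest knockout value of a day stayed below the lowest wild-type value of that day: 43.9 against 109 at day 0, 96.2 against 184 at day 2 and 55.6 against 149 at day 4.

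The libraries separated mainly between uninfected and infected lungs. The first principal component of log2 CPM held 39.0% of the variance, and its group means were -69.2 (wild type) and -65.7 (knockout) at day 0, 69.9 and 46.0 at day 2, and 37.6 and -18.6 at day 4. Knockout lungs thus lay nearer to the uninfected lungs on this axis at day 4 than wild-type lungs did, with no overlap between the 5 and 5 libraries (-30.0 to -8.95 against 16.9 to 72.9). A few libraries stood apart from their groups. Wild-type library 3 of day 4 lay at 72.9, within the range of wild-type day 2 (53.1 to 89.9), while the other 4 lay between 16.9 and 37.1. Its Y-linked count of 634 was that of a male. Knockout library 4 of day 0 lay at -50.8, while the lowest knockout value of that day was -74.5.

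**Figure D2:**
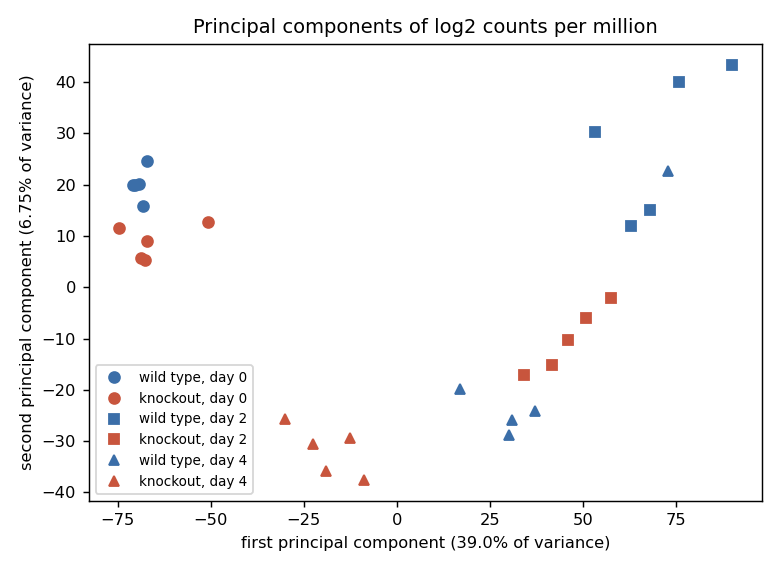
First and second principal components of log2 CPM in the 30 libraries, 39.0% and 6.75% of the variance, colored by genotype with a marker for each day. Uninfected lungs of both genotypes lie on the left, day 2 lungs on the right, and knockout lungs of day 4 lie between -30.0 and -8.95 on the first component, left of the wild-type lungs of that day.

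Inflammatory mediators were higher in wild-type lungs at day 2 of infection than at day 0. The groups include no mock-treated animals at day 2 or day 4. Effects of the procedure or of the sampling day therefore cannot be told apart from infection. Each of the 26 measured cytokine and chemokine genes rose (26 adjusted over the list alone, median 5.71, adjusted p = 1.57e-17, and adjusted p = 0.0238 with an estimated correlation). Cxcl1, a chemokine that draws neutrophils, rose 975-fold (interval 333 to 4730), Il6 at least 328-fold and Csf3, the growth factor of granulocytes, at least 182-fold. Il1rn, the interleukin 1 receptor antagonist, rose by 6.23 ± 0.46. Neutrophil markers rose in 20 of 20 genes (20 adjusted over the list alone, median 4.76, adjusted p = 1.27e-15, and adjusted p = 0.0593 with an estimated correlation), among them the formyl peptide receptor Fpr1 (4.17 ± 0.31) and Clec4e (6.00 ± 0.52). Monocyte and recruited macrophage markers rose in 19 of 19 genes (19 adjusted over the list alone, median 2.90, adjusted p = 3.69e-17, and adjusted p = 0.013 with an estimated correlation). Cd68 was at 2.18 ± 0.13 and the complement genes C1qa, C1qb and C1qc at 2.90 ± 0.19, 3.20 ± 0.19 and 2.96 ± 0.18. Antimicrobial and acute-phase genes rose in 18 of 22, and 2 fell (19 up and 3 down adjusted over the list alone, median 3.03, adjusted p = 1.66e-11, and adjusted p = 0.00773 with an estimated correlation). Lcn2, which binds bacterial siderophores, rose by 5.73 ± 0.32, Chil1 by 4.07 ± 0.18 and the acute-phase protein gene Saa3 by 9.69 ± 1.06.

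Interferon-gamma response genes rose in 22 of 22 (22 adjusted over the list alone, median 3.70, adjusted p = 2.15e-16, and adjusted p = 0.108 with an estimated correlation). Type I interferon-stimulated genes rose in 22 of 22 (22 adjusted over the list alone, median 3.01, adjusted p = 1.27e-15, and adjusted p = 0.0769 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 5.14 ± 0.48, Isg15 by 4.99 ± 0.44 and the chemokine Cxcl11 at least 734-fold. All 26 cell cycle genes rose (26 adjusted over the list alone, median 3.04, adjusted p = 6.42e-17, and adjusted p = 0.0134 with an estimated correlation). The mitotic kinase Cdk1 was at 4.23 ± 0.36 and the ribonucleotide reductase subunit Rrm2 at 3.10 ± 0.26. Inflammasome genes rose in 12 of 13 (13 adjusted over the list alone, median 2.13, adjusted p = 1.07e-06, and adjusted p = 0.0186 with an estimated correlation). Circadian clock genes fell in 9 of 14 while 1 rose (10 down and 1 up adjusted over the list alone, median -1.44, adjusted p = 0.000456, and adjusted p = 0.0186 with an estimated correlation). Nr1d1, a repressor within the clock, was at -2.05 ± 0.15. The time of day of sampling is not given in the sources used here.

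Genes of resident cells fell in wild-type lungs over the same days, as shares of a library. The rise of inflammatory transcripts would by itself lower such shares, so a loss of these cells or of their expression is not shown. Endothelial markers fell in 17 of 19 (18 adjusted over the list alone, median -0.90, adjusted p = 3.03e-07, and adjusted p = 0.133 with an estimated correlation). The VEGF receptor Kdr was at -1.75 ± 0.17 and the endothelin receptor Ednrb at -2.18 ± 0.20. Alveolar type 1 markers fell in 11 of 15 (11 adjusted over the list alone, median -0.90, adjusted p = 0.000108, and adjusted p = 0.301 with an estimated correlation). Ciliated cell markers fell in 11 of 15 (11 adjusted over the list alone, median -1.57, adjusted p = 0.000168, and adjusted p = 0.152 with an estimated correlation). Cardiac muscle genes fell in 9 of 11 (9 adjusted over the list alone, median -2.31, adjusted p = 0.000153, and adjusted p = 0.231 with an estimated correlation). Erythroid genes fell in 7 of 8 (7 adjusted over the list alone, median -2.29, adjusted p = 0.000537, and adjusted p = 0.231 with an estimated correlation). The hemoglobin gene Hba-a2 was at -1.81 ± 0.29, so transcripts of heart muscle and red cells differed between the days too. In total 6580 of 14544 tested genes changed at an adjusted p under 0.05, 3353 up and 3227 down, and 25 of the 38 lists were called. The groups did not overlap in 32.8% of genes, against 0.794% by chance.

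At day 4 wild-type lungs still differed from day 0 in 5393 genes, 2916 up and 2477 down, and 23 lists were called. All 26 cell cycle genes were higher (26 adjusted over the list alone, median 3.32, adjusted p = 9.34e-22, and adjusted p = 0.00648 with an estimated correlation). All 19 monocyte and recruited macrophage markers were higher (19 adjusted over the list alone, median 2.30, adjusted p = 1.3e-19, and adjusted p = 0.00648 with an estimated correlation). Fibroblast and extracellular matrix genes were higher in 13 of 22 and lower in 2 (13 up and 2 down adjusted over the list alone, median 0.71, adjusted p = 8.47e-07, and adjusted p = 0.0139 with an estimated correlation). The collagen gene Col1a1 was at 2.53 ± 0.19 and Col3a1 at 1.80 ± 0.10. Arg1, which degrades arginine, was up by 8.80 ± 0.98. Antimicrobial genes were higher in 17 of 22 and lower in 2 (18 up and 2 down adjusted over the list alone, median 2.10, adjusted p = 1.67e-08, and adjusted p = 0.0125 with an estimated correlation). Their median was 1.84 with the gene that had 0 counts at day 0 set at its bound. Endothelial markers were lower in 16 of 19 (16 adjusted over the list alone, median -0.97, adjusted p = 3.11e-10, and adjusted p = 0.0756 with an estimated correlation). Males at day 4 were compared with females at day 0, so sex and time cannot be told apart in these comparisons. The same holds for day 4 against day 2, and for day 4 against either earlier day in the knockout.

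From day 2 to day 4 interferon and cytokine genes declined in wild-type lungs. All 22 interferon-gamma response genes fell (22 adjusted over the list alone, median -2.20, adjusted p = 1.96e-26, and adjusted p = 0.0334 with an estimated correlation). Irf1 was at -1.63 ± 0.21. Type I interferon-stimulated genes fell in 19 of 22 (22 adjusted over the list alone, median -1.84, adjusted p = 1.96e-26, and adjusted p = 0.0161 with an estimated correlation). Cytokines fell in 20 of 26 (23 adjusted over the list alone, median -2.05, adjusted p = 2.46e-25, and adjusted p = 0.0107 with an estimated correlation). The chemokine Ccl4 was at -4.13 ± 0.51. Immediate early genes, which respond to growth factor signals and to handling, fell in 10 of 16 (11 adjusted over the list alone, median -0.87, adjusted p = 1.5e-10, and adjusted p = 0.0107 with an estimated correlation). Matrix genes rose in 9 of 22 (11 adjusted over the list alone, median 0.46, adjusted p = 7e-08, and adjusted p = 0.0107 with an estimated correlation). Col1a1 was at 1.58 ± 0.19 and Fn1 (fibronectin) at 1.09 ± 0.16, and the lipid carrier gene Apoe rose by 3.54 ± 0.28. Of the 26 cell cycle genes 0 changed with edgeR, and the list was not called (adjusted p = 0.272, and adjusted p = 0.781 with an estimated correlation). In all 1195 genes changed, 480 up and 715 down. The count was 766 without wild-type library 2 of day 2 and 2046 without wild-type library 3 of day 4.

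Knockout lungs differed from their day 0 in 5584 genes at day 2, 2973 up and 2611 down. All 26 cell cycle genes rose (26 adjusted over the list alone, median 3.21, adjusted p = 8.68e-22, and adjusted p = 0.00725 with an estimated correlation). All 19 monocyte and recruited macrophage markers rose (19 adjusted over the list alone, median 2.24, adjusted p = 9.03e-18, and adjusted p = 0.00725 with an estimated correlation). Antimicrobial genes rose in 17 of 22 while 1 fell (17 up and 1 down adjusted over the list alone, median 2.04, adjusted p = 6.23e-10, and adjusted p = 0.00725 with an estimated correlation). Cytokine genes rose in 21 of 26 (23 adjusted over the list alone, median 2.98, adjusted p = 6.46e-12, and adjusted p = 0.104 with an estimated correlation). Il1rn was at 3.68 ± 0.40 and the neutrophil chemokine Cxcl5 at 6.23 ± 0.77. Neutrophil markers rose in 19 of 20 (20 adjusted over the list alone, median 2.85, adjusted p = 8.65e-12, and adjusted p = 0.121 with an estimated correlation). Gbp10, a guanylate-binding protein induced by interferon, rose 202-fold (interval 55.6 to 1670). All 11 cardiac muscle genes fell (11 adjusted over the list alone, median -2.41, adjusted p = 1.95e-06, and adjusted p = 0.174 with an estimated correlation). The cardiac myosin gene Myh6 was at -4.42 ± 0.51. The genotypes shared 2449 of the genes that rose and 1893 of those that fell by day 2, where independent lists would share 685 and 579.

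At day 4 the knockout differed from its day 0 in 1697 genes, 999 up and 698 down. Monocyte and recruited macrophage markers were higher in 16 of 19 (16 adjusted over the list alone, median 1.86, adjusted p = 5.04e-28, and adjusted p = 0.00146 with an estimated correlation). The membrane gene Ms4a7 was at 3.85 ± 0.28 and Cd68 at 1.86 ± 0.13. Cell cycle genes were higher in 17 of 26 (20 adjusted over the list alone, median 1.54, adjusted p = 7.42e-15, and adjusted p = 0.0284 with an estimated correlation). The cyclin gene Ccna2 was at 2.57 ± 0.39. Cytokines were higher in 2 of 26 (2 adjusted over the list alone, median 0.42, adjusted p = 0.00522, and adjusted p = 0.417 with an estimated correlation). Neutrophil markers were higher in 2 of 20 (2 adjusted over the list alone, median 0.37, adjusted p = 0.00759, and adjusted p = 0.465 with an estimated correlation). MHC class II genes, which present antigen to helper T cells, were higher in 8 of 17 (11 adjusted over the list alone, median 1.11, adjusted p = 8.55e-08, and adjusted p = 0.101 with an estimated correlation). Alveolar macrophage markers were higher in 10 of 18 and lower in 2 (10 up and 2 down adjusted over the list alone, median 0.85, adjusted p = 2.92e-05, and adjusted p = 0.138 with an estimated correlation). The scavenger receptor Marco was at 1.55 ± 0.20. Elastin (Eln) was up by 2.58 ± 0.25. Cardiac muscle genes were lower in 9 of 11 (9 adjusted over the list alone, median -1.50, adjusted p = 4.66e-07, and adjusted p = 0.138 with an estimated correlation).

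Between day 2 and day 4 proliferative and inflammatory transcripts fell in knockout lungs. Cell cycle genes fell in 25 of 26 (25 adjusted over the list alone, median -1.54, adjusted p = 4.77e-18, and adjusted p = 0.0258 with an estimated correlation). The replication helicase subunit Mcm5 was at -2.04 ± 0.21 and Pcna at -1.11 ± 0.12. Neutrophil markers fell in 19 of 20 (20 adjusted over the list alone, median -2.38, adjusted p = 2.06e-14, and adjusted p = 0.0875 with an estimated correlation). Cytokines fell in 19 of 26 (21 adjusted over the list alone, median -2.75, adjusted p = 1.83e-14, and adjusted p = 0.0646 with an estimated correlation). Antimicrobial genes fell in 16 of 22 while 2 rose (17 down and 4 up adjusted over the list alone, median -1.21, adjusted p = 1.07e-07, and adjusted p = 0.0333 with an estimated correlation). The acute-phase gene Saa1 was at -5.29 ± 0.67 and Il1rn at -2.87 ± 0.38. Alveolar macrophage markers rose in 14 of 18 (15 adjusted over the list alone, median 0.91, adjusted p = 1.36e-10, and adjusted p = 0.0378 with an estimated correlation). Cidec was at 1.97 ± 0.29. Alveolar type 2 markers rose in 10 of 15 (10 adjusted over the list alone, median 0.73, adjusted p = 3.79e-07, and adjusted p = 0.266 with an estimated correlation). The surfactant protein gene Sftpc was at 0.75 ± 0.14. Map2k2 itself fell (-0.91 ± 0.13, adjusted p = 8.89e-06). In all 2890 genes changed, 1122 up and 1768 down.

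Before infection the genotypes differed in 45 genes, 25 higher and 20 lower in the knockout. Pianp was at least 29.7-fold higher and the complement protease gene C1rb at least 19.3-fold higher, and C1s2, another complement protease gene, was 58.2-fold (interval 15.8 to 486) higher. These 3 genes lie on chromosome 6 at 124996694 to 125003096, 124570294 to 124581171 and 124624625 to 124636085. Ggcx, the carboxylase that acts with vitamin K, was higher by 1.87 ± 0.25 and Slc35f6 by 1.76 ± 0.16. Mndal, an interferon-inducible gene, was lower (-3.63 ± 0.58), as was the lysosomal membrane gene Gpr137b (-1.22 ± 0.20). At day 2 Mndal was lower too (-4.58 ± 0.51) and C1s2 higher (5.28 ± 0.68). Of the genes called at day 0, 21 were called at all 3 days, and 20 of these in one direction. The exception was Spp1 (osteopontin), at 1.44 ± 0.30 at day 0, and lower at days 2 and 4, where it was at -1.92 at day 4, a value looked up after the day 0 call was seen. Its day 0 call ended without any one of 5 libraries (adjusted p = 0.0619 to 0.0919): wild-type libraries 1 to 4 (0.0919, 0.0619, 0.0625 and 0.0832) and knockout library 5 (0.0822).

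The list of antimicrobial and acute-phase genes was called higher in the knockout at day 0, with 2 of 22 genes past the threshold, Lcn2 and Chil1 (7 adjusted over the list alone, median 0.54, adjusted p = 3.85e-07, and adjusted p = 0.0557 with an estimated correlation). Knockout library 4, which stands apart, held 1366 Lcn2 counts where the next highest of its group held 677. Saa3, not past the threshold (adjusted p = 0.15), was at 43.5 ± 89.3 CPM (SD) in the knockout. The median of the list was 0.456 without knockout library 4, 0.374 without knockout library 3 and 0.349 without the 3 libraries that stand apart. The Lcn2 call ended without any one of 5 libraries, wild-type libraries 1 to 4 and knockout library 4 (adjusted p = 0.0556 to 0.0923), and without knockout libraries 3 and 4 together (0.182). Chil1, which binds chitin, was higher by 1.06 ± 0.16. T cell markers tended lower with 0 of 18 past the threshold with edgeR (1 adjusted over the list alone, median -0.51, adjusted p = 4.8e-05, and adjusted p = 0.684 with an estimated correlation). Club and goblet cell markers were called higher with 1 gene past the threshold, the airway secretory gene Bpifa1 (4 adjusted over the list alone, median 0.38, adjusted p = 0.0206, and adjusted p = 0.853 with an estimated correlation), and knockout library 3 held 1694 Bpifa1 counts where the next highest held 226. The Bpifa1 call ended without any one of 5 libraries, wild-type libraries 1, 3, 4 and 5 and knockout library 3 (0.0868 to 0.162), and with voom (0.322). Without knockout library 3 the list had an adjusted p of 0.219, and without that library, knockout library 4 of day 0 and wild-type library 3 of day 4 it had 0.594. NK and cytotoxic cell markers had 0 of 12 past the threshold (0 adjusted over the list alone, median 0.55, adjusted p = 0.0293, and adjusted p = 0.853 with an estimated correlation). Immediate early genes had 0 of 16 past it with edgeR (2 adjusted over the list alone, median -0.34, adjusted p = 0.0348, and adjusted p = 0.785 with an estimated correlation). Leaving out any one of 7 libraries ended the NK call (adjusted p = 0.0524 to 0.225), and any one of 4 the immediate early call (0.0621 to 0.217). Cytokine genes were not called at day 0, with a median of 0.47, or 0.35 with the genes that had 0 counts in a group at their bound. An unadjusted p under 0.05 with edgeR was seen in 921 of 14544 genes, where a share of 0.05 is expected with no difference. After adjustment 45 remained. The count was 94 with the DESeq2 Wald test and 109 with limma voom.

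At day 2 inflammatory genes were lower in the knockout. Cytokine and chemokine genes were lower in 13 of 26 (18 adjusted over the list alone, median -1.42, adjusted p = 5.17e-13, and adjusted p = 0.208 with an estimated correlation). Cxcl1 was at -2.07 ± 0.44, Il1a at -1.76 ± 0.32 and Ptgs2 (cyclooxygenase 2) at -1.61 ± 0.34. Csf3 was at -3.68 ± 0.79. Type I interferon-stimulated genes were lower in 15 of 22 (21 adjusted over the list alone, median -1.19, adjusted p = 5.17e-13, and adjusted p = 0.239 with an estimated correlation). Ifit2 was at -1.78 ± 0.38 and Usp18 at -1.23 ± 0.29. Immediate early genes were lower in 11 of 16 (11 adjusted over the list alone, median -0.70, adjusted p = 5.05e-10, and adjusted p = 0.0409 with an estimated correlation). Fos was at -1.57 ± 0.25, Junb at -1.08 ± 0.17 and Egr1 at -2.24 ± 0.42, all transcription factors. This list also holds genes of handling stress. Growth factor signals and handling cannot be told apart by these values. Neutrophil markers were lower in 5 of 20 (13 adjusted over the list alone, median -0.99, adjusted p = 7.13e-09, and adjusted p = 0.239 with an estimated correlation). Fpr1 was at -1.25 ± 0.26 and Ly6g at -3.26 ± 0.74. Hypoxia and glycolysis genes were lower in 4 of 17 (10 adjusted over the list alone, median -0.53, adjusted p = 2.57e-07, and adjusted p = 0.239 with an estimated correlation). Hif1a was at -0.97 ± 0.18 and the glucose transporter Slc2a1 at -1.53 ± 0.32.

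Targets of ERK were lower in 5 of 19 and higher in 1 at day 2 (7 down and 3 up adjusted over the list alone, median -0.39, adjusted p = 0.0372, and adjusted p = 0.282 with an estimated correlation). Egr1 counts in this list as well as among the immediate early genes, and the phosphatase Dusp6, which acts on ERK, was at -0.58 ± 0.14 and Ier3 at -0.56 ± 0.12. The ERK target call ended without wild-type library 1 (adjusted p = 0.0708), wild-type library 3 (0.0855) or knockout library 4 (0.0657), in a fit of these 10 libraries alone (0.107) and with libraries thinned to 1 total (0.0551). Coagulation genes were lower in 4 of 16 (6 adjusted over the list alone, median -0.41, adjusted p = 0.00203, and adjusted p = 0.244 with an estimated correlation). Tissue factor (F3) was at -1.70 ± 0.30. Matrix metalloproteinases were lower in 4 of 16 (8 down and 2 up adjusted over the list alone, median -0.81, adjusted p = 0.00258, and adjusted p = 0.239 with an estimated correlation). Mmp3 was at -1.65 ± 0.25. Transitional alveolar genes were lower in 3 of 18 (6 adjusted over the list alone, median -0.32, adjusted p = 0.00279, and adjusted p = 0.282 with an estimated correlation). Matrix genes were lower in 5 of 22 and higher in 1 (7 down and 1 up adjusted over the list alone, median -0.24, adjusted p = 0.0233, and adjusted p = 0.282 with an estimated correlation). The matrix protein tenascin C (Tnc) was at -1.83 ± 0.37. This call ended without wild-type library 1 (0.0708) or library 3 (0.0554).

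Several lists of resident lung cell and lymphocyte markers were called higher in the knockout at day 2, each with a minority of its genes past the threshold. Values are shares of a library, so fewer inflammatory transcripts in the knockout would by themselves raise these lists. Alveolar type 1 markers were higher in 4 of 15 (7 adjusted over the list alone, median 0.37, adjusted p = 0.000156, and adjusted p = 0.36 with an estimated correlation). Igfbp2 was at 1.40 ± 0.27. Alveolar type 2 markers were higher in 2 of 15 (5 adjusted over the list alone, median 0.34, adjusted p = 0.00516, and adjusted p = 0.461 with an estimated correlation). Sftpc was at 0.60 ± 0.14. B cell markers were higher in 3 of 13 (4 adjusted over the list alone, median 0.95, adjusted p = 0.00126, and adjusted p = 0.269 with an estimated correlation). Ighd (immunoglobulin D heavy chain) was at 1.90 ± 0.36. Erythroid genes were called higher with 1 of 8 past the threshold (5 adjusted over the list alone, median 0.82, adjusted p = 0.00617, and adjusted p = 0.391 with an estimated correlation). Endothelial markers were called higher with 1 of 19 past the threshold (1 adjusted over the list alone, median 0.24, adjusted p = 0.00663, and adjusted p = 0.45 with an estimated correlation). This call ended without wild-type library 2 (adjusted p = 0.0587). Of 12 NK and cytotoxic cell markers 1 was higher (1 adjusted over the list alone, median 0.45, adjusted p = 0.0132, and adjusted p = 0.409 with an estimated correlation). Club and goblet cell markers were higher in 3 of 15 (4 adjusted over the list alone, median 0.42, adjusted p = 0.0164, and adjusted p = 0.461 with an estimated correlation). Leaving out any one of 2 libraries ended the NK call (adjusted p = 0.0562 to 0.248), and any one of 3 the club and goblet call (0.0569 to 0.0981).

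Further lists were called lower at day 2, each with a call that ended without single libraries. Monocyte markers were lower in 3 of 19 (5 adjusted over the list alone, median -0.29, adjusted p = 0.0304, and adjusted p = 0.461 with an estimated correlation). Alternative macrophage genes were lower in 2 of 15 and higher in 1 (2 down and 1 up adjusted over the list alone, median -0.37, adjusted p = 0.0279, and adjusted p = 0.239 with an estimated correlation). Resolution genes were lower in 1 of 16 (3 adjusted over the list alone, median -0.09, adjusted p = 0.0461, and adjusted p = 0.239 with an estimated correlation). Cholesterol synthesis genes were lower in 1 and higher in 1 (1 down and 1 up adjusted over the list alone, median -0.26, adjusted p = 0.0413, and adjusted p = 0.45 with an estimated correlation). Interferon-gamma response genes had 0 of 22 past the threshold with edgeR (0 adjusted over the list alone, median -0.48, adjusted p = 0.0243, and adjusted p = 0.533 with an estimated correlation). Inflammasome genes had 0 of 13 past it (0 adjusted over the list alone, median -0.38, adjusted p = 0.0413, and adjusted p = 0.36 with an estimated correlation). Leaving out any one of 4 libraries ended the monocyte call (adjusted p = 0.0557 to 0.122). The same held for 2 libraries with alternative macrophage genes (0.0565 to 0.0569), 5 with resolution genes (0.0569 to 0.101) and 5 with cholesterol genes (0.0569 to 0.15). It held for 4 with interferon-gamma genes (0.0574 to 0.344) and 5 with inflammasome genes (0.0526 to 0.199).

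In all 934 genes differed at day 2, 481 higher and 453 lower in the knockout, and 213 and 173 of these differed the same way at day 4, where independent lists would share 39.2 and 45.3. A fit of these 10 libraries alone called 554, 175 higher and 379 lower, and voom called 367 higher and 592 lower, so the balance of directions depends on the fit. Leaving out a single library gave 440 (wild-type library 2), 474 (wild-type library 3), 612, 557 and 491 (knockout libraries 3, 4 and 5), and testing without a filter on low counts gave 534.

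At day 4 the knockout lungs held fewer transcripts of proliferation. Cell cycle genes were lower in 24 of 26 (24 adjusted over the list alone, median -1.69, adjusted p = 3.2e-19, and adjusted p = 0.0188 with an estimated correlation). The thymidylate synthase gene Tyms was at -1.88 ± 0.20, Mcm5 at -1.75 ± 0.21 and Rrm2 at -1.80 ± 0.24. Tyms was at 82.4 ± 11.4 CPM (SD, n = 5) in wild type and 22.4 ± 5.18 in the knockout. Neutrophil markers were lower in 18 of 20 (18 adjusted over the list alone, median -2.26, adjusted p = 3.93e-10, and adjusted p = 0.17 with an estimated correlation). Csf3r, the receptor for the Csf3 product, was at -1.91 ± 0.35 and Hdc, which makes histamine, at -1.20 ± 0.18. Cytokines were lower in 14 of 26 (17 adjusted over the list alone, median -1.68, adjusted p = 3.96e-07, and adjusted p = 0.242 with an estimated correlation). Cxcl2 was at -4.92 ± 0.93, Cxcl1 at -2.78 ± 0.53 and Il1rn at -2.09 ± 0.37. Csf3 was at least 22.2-fold lower, a call that ended with voom (adjusted p = 0.0568). Wild-type library 3 held 60 of its 83 counts, and the bound without that library was 7.44. Without it 8 of 26 cytokine genes were past the threshold, Cxcl2 was at -2.81, Cxcl1 at -2.09 and Il1rn at -1.42. Hypoxia and glycolysis genes were lower in 14 of 17 and higher in 1 (15 down and 1 up adjusted over the list alone, median -0.89, adjusted p = 2.68e-10, and adjusted p = 0.0651 with an estimated correlation). Ankrd37 was at -2.69 ± 0.29, Eno1 at -1.36 ± 0.16 and the lactate dehydrogenase gene Ldha at -0.87 ± 0.12. Arg1 was at -4.96 ± 0.72.

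Matrix and repair genes were lower in the knockout at day 4 as well. Matrix genes were lower in 12 of 22 and higher in 2 (12 down and 3 up adjusted over the list alone, median -0.58, adjusted p = 0.000158, and adjusted p = 0.0931 with an estimated correlation). Col1a1 was at -1.38 ± 0.18, Col3a1 at -0.81 ± 0.10 and the protease inhibitor Timp1 at -3.64 ± 0.51 (-2.64 without wild-type library 3). Transitional alveolar genes were lower in 11 of 18 and higher in 2 (12 down and 2 up adjusted over the list alone, median -0.69, adjusted p = 3.82e-06, and adjusted p = 0.0937 with an estimated correlation). The keratin genes Krt8 and Krt18 were at -0.84 ± 0.14 and -0.77 ± 0.12, and Sfn at -2.32 ± 0.32. Monocyte and recruited macrophage markers were lower in 9 of 19 and higher in 1 (14 down and 1 up adjusted over the list alone, median -0.64, adjusted p = 6.62e-06, and adjusted p = 0.179 with an estimated correlation). C1qc was at -1.01 ± 0.16 and the lipopolysaccharide receptor gene Cd14 at -1.69 ± 0.34. Coagulation genes were lower in 6 of 16 (6 adjusted over the list alone, median -0.53, adjusted p = 0.00475, and adjusted p = 0.242 with an estimated correlation). F13a1 was at -2.63 ± 0.38. Antimicrobial genes were lower in 8 of 22 and higher in 3 (10 down and 3 up adjusted over the list alone, median -0.71, adjusted p = 0.0131, and adjusted p = 0.242 with an estimated correlation). Lrg1 was at -1.16 ± 0.15 and the lysozyme gene Lyz1 at 1.73 ± 0.26. Type I interferon genes were lower in 3 of 22 (3 adjusted over the list alone, median -0.67, adjusted p = 0.00177, and adjusted p = 0.511 with an estimated correlation). Metalloproteinase genes were lower in 7 of 16 and higher in 2 (7 down and 3 up adjusted over the list alone, median -0.77, adjusted p = 0.0475, and adjusted p = 0.317 with an estimated correlation). Leaving out 1 library ended the calls of the antimicrobial list (wild-type library 3, 0.0524), and of the interferon and metalloproteinase lists (wild-type library 2, 0.0552 for both). The metalloproteinase call also ended with voom (0.136) and with the replicate block (0.0524). Without wild-type library 3 the metalloproteinase median was -0.189 and the coagulation median -0.248, and 1 type I interferon gene was past the threshold.

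Lists of resident cell and lymphocyte markers were called higher in the knockout at day 4. The same limit of shares holds here as at day 2. Alveolar macrophage markers were higher in 11 of 18 (13 adjusted over the list alone, median 0.86, adjusted p = 3.92e-09, and adjusted p = 0.0645 with an estimated correlation). The ribonuclease genes Ear1 and Ear2 were at 1.81 ± 0.24 and 1.41 ± 0.14. Alveolar type 1 markers were higher in 8 of 15 (10 adjusted over the list alone, median 0.44, adjusted p = 6.63e-06, and adjusted p = 0.242 with an estimated correlation). Ager was at 0.79 ± 0.13. Alveolar type 2 markers were higher in 9 of 15 (9 adjusted over the list alone, median 0.48, adjusted p = 3.89e-05, and adjusted p = 0.317 with an estimated correlation). Sftpc was at 0.66 ± 0.14. Endothelial markers were higher in 8 of 19 (9 adjusted over the list alone, median 0.42, adjusted p = 1.54e-05, and adjusted p = 0.242 with an estimated correlation). Ednrb was at 1.24 ± 0.20. Ciliated cell markers were higher in 4 of 15 (4 adjusted over the list alone, median 0.58, adjusted p = 0.00914, and adjusted p = 0.319 with an estimated correlation). Circadian clock genes were higher in 8 of 14 and lower in 1 (8 up and 1 down adjusted over the list alone, median 0.84, adjusted p = 0.000154, and adjusted p = 0.0229 with an estimated correlation). Nr1d1 was at 1.08 ± 0.15, Tef at 1.30 ± 0.19 and Dbp at 1.92 ± 0.34. T cell markers were higher in 3 of 18 (5 adjusted over the list alone, median 0.69, adjusted p = 0.000378, and adjusted p = 0.242 with an estimated correlation). NK and cytotoxic cell markers were higher in 4 of 12 (6 adjusted over the list alone, median 1.03, adjusted p = 0.000698, and adjusted p = 0.242 with an estimated correlation). B cell markers were higher in 4 of 13 (6 adjusted over the list alone, median 0.97, adjusted p = 0.00257, and adjusted p = 0.242 with an estimated correlation). Erythroid genes were higher in 7 of 8 (8 adjusted over the list alone, median 1.53, adjusted p = 5.06e-08, and adjusted p = 0.0937 with an estimated correlation). Hba-a2 was at 1.46 ± 0.29 (2.09 without wild-type library 3), so red cell transcripts differed beside these groups. Without wild-type library 3 the threshold was passed by 4 alveolar type 2 markers (median 0.307), 5 alveolar type 1 markers (median 0.257), 12 endothelial markers, 2 B cell markers and, with edgeR, 0 T cell markers. The ciliated median was 0.357, and all of these lists were still called (adjusted p of 0.0266 or less). Cardiac muscle genes, not called with all libraries, were called higher without that library (3 of 11 past the threshold, median 0.934, adjusted p = 0.0141 with camera).

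The hyaluronan synthase gene Has2 was at -4.52 ± 0.95 and Colq, the collagen tail of acetylcholinesterase, at 4.20 ± 0.73. In all 2639 genes differed at day 4, 1184 higher and 1455 lower, 419 and 525 of them at least 2-fold. The count was 1998 without the 3 libraries that stand apart, and 69.1% of calls were shared. Wild-type library 3 of day 4 moved further medians beside those above: without it the neutrophil median was -1.24, the erythroid median 2.60 and the cytokine median -1.06. The 24 cell cycle genes lower with it were the 24 lower without it, at a list median of -1.77. Of ERK target genes 5 were lower and 4 higher, among them Dusp6 (-0.78 ± 0.14) and Spry1 (0.99 ± 0.14), and the list was not called (adjusted p = 0.437). The other uncalled lists at day 4, 16 in number, had adjusted p between 0.0757 (MHC class II) and 0.955 (RAS-RAF-MEK-ERK pathway, immature neutrophil and upper airway genes). Median, mean and test differed in sign for 3 of the uncalled lists: immediate early, RAS-RAF-MEK-ERK pathway and upper airway genes.

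**Figure D3:**
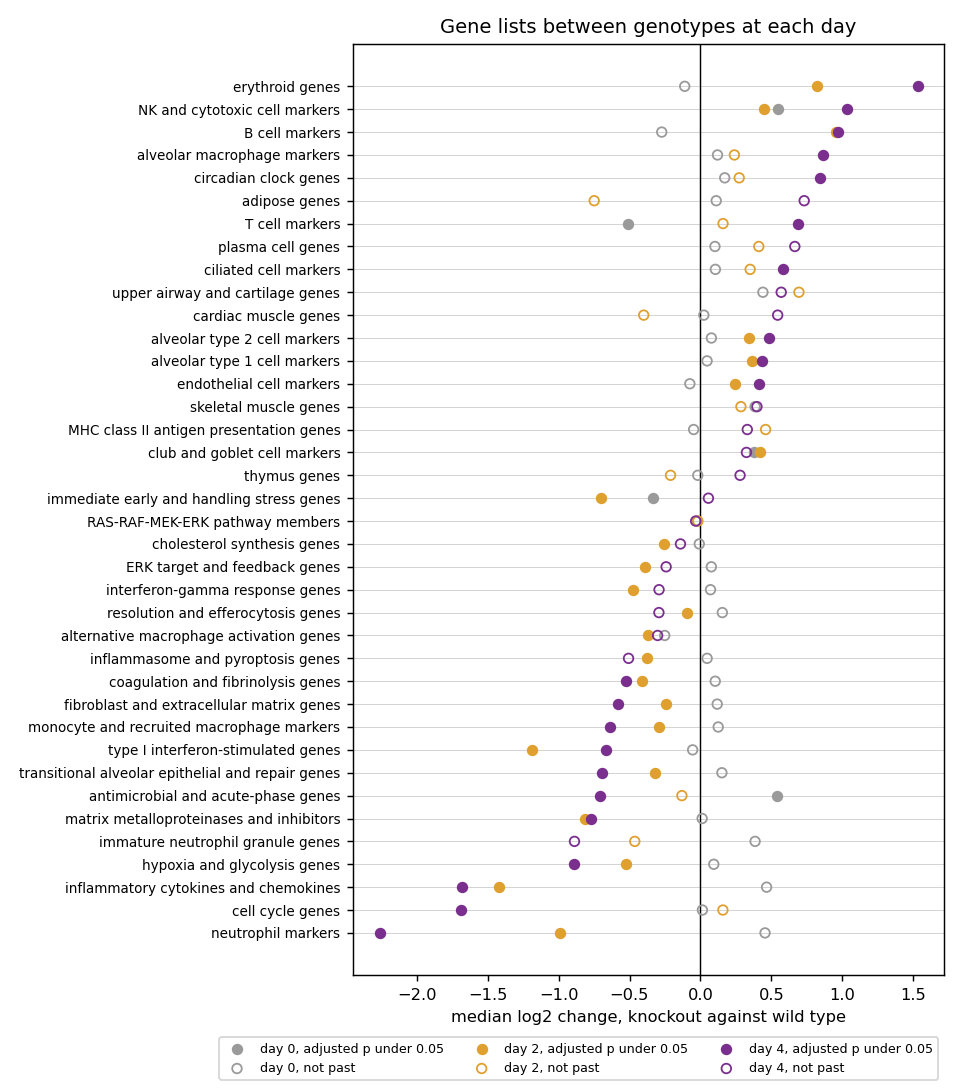
Median log2 change between knockout and wild type for each of 38 gene lists (vertical axis) at days 0, 2 and 4, with filled points for an adjusted p under 0.05 and open points for the others. At day 4 neutrophil markers (-2.26) and cell cycle genes (-1.69) lie on the left and erythroid genes (1.53) on the right.

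**Figure D4:**
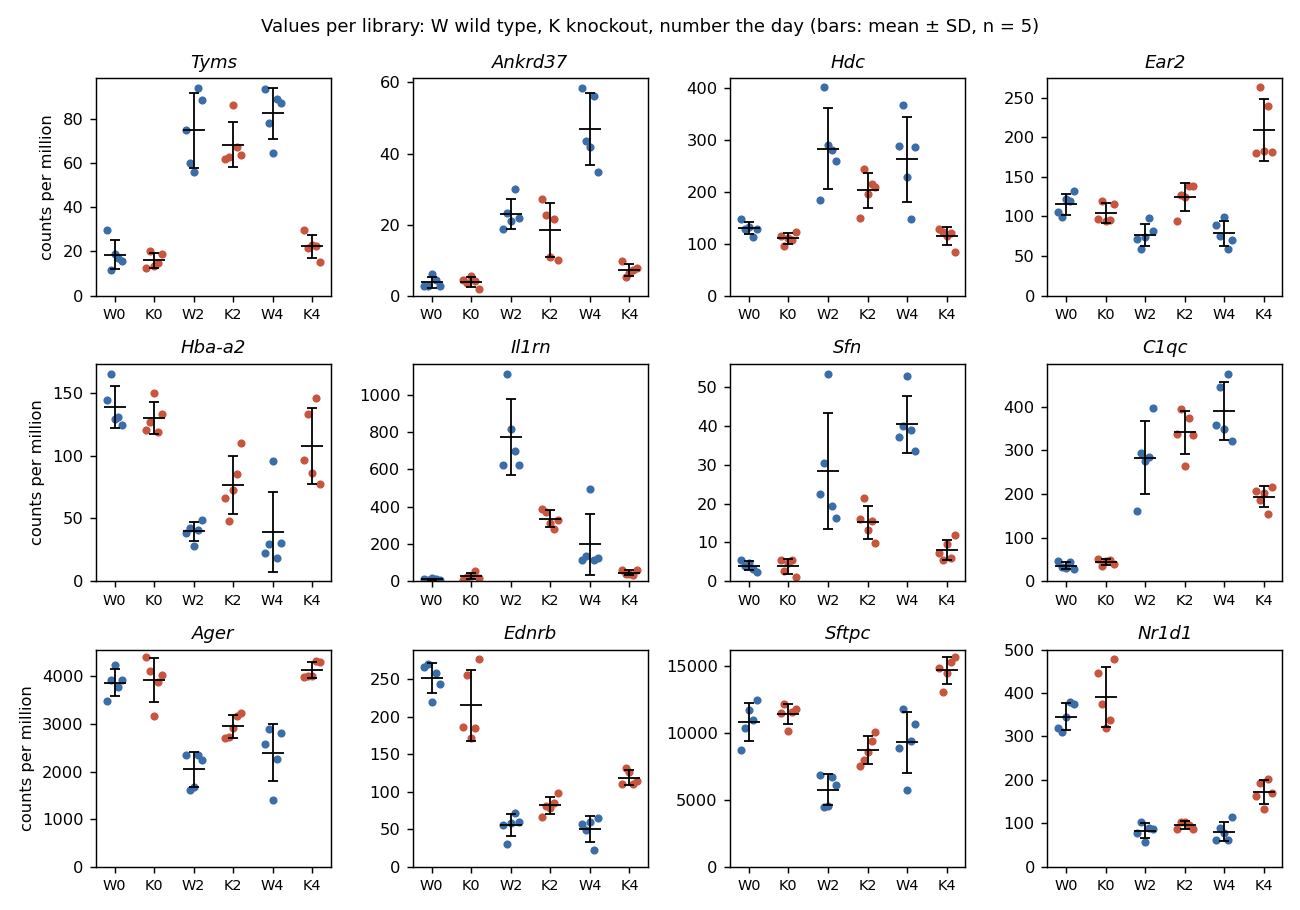
CPM of 12 genes in each library of the 6 groups, with the mean and SD of 5 libraries, chosen after the data were seen as the member with the smallest p of each of the 12 lists with the smallest p at day 4. Tyms is at 82.4 in wild type and 22.4 in the knockout at day 4.

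The responses of the genotypes differed in 24 genes from day 0 to day 2. The difference (knockout response minus wild-type response) was -1.46 ± 0.25 for Junb, -1.03 ± 0.18 for Ier3 and -2.57 ± 0.42 for Spp1, which had 1933 and 6430 counts over the wild-type groups and 5841 and 3345 over the knockout groups. Cytokines had 0 genes past the threshold with edgeR (13 adjusted over the list alone, median -1.98, adjusted p = 4.75e-15, and adjusted p = 0.0838 with an estimated correlation). Neutrophil markers had 0 of 20 past it with edgeR (2 adjusted over the list alone, median -1.58, adjusted p = 1.19e-09, and adjusted p = 0.174 with an estimated correlation). The knockout baseline of these differences includes library 4 of day 0, which stands apart. Its Il1rn was at 52.3 CPM, and the others of its group were at 9.16 to 28.6. The difference was past the threshold and positive in 1 of 13 B cell markers (4 adjusted over the list alone, median 1.15, adjusted p = 7.59e-05, and adjusted p = 0.174 with an estimated correlation). An unadjusted p under 0.05 with edgeR was seen in 1837 of 14544 genes, where a share of 0.05 is expected with no difference. The count ranged from 3 to 74 when single libraries were left out, and was 232 with DESeq2 and 93 with voom.

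From day 0 to day 4 the responses differed in 1084 genes, 458 up and 626 down. Since day 4 animals were male and day 0 animals female, a genotype effect that differs by sex cannot be told apart from a different response. More were up than down with voom (662 and 555) and in a fit of these 4 groups alone (563 and 531). The difference was past the threshold and negative in 18 of 26 cell cycle genes (22 adjusted over the list alone, median -1.57, adjusted p = 4.29e-17, and adjusted p = 0.0336 with an estimated correlation). Tyms was at -1.65 ± 0.29 and Cdk1 at -2.53 ± 0.51. It was past the threshold and negative in 12 of 20 neutrophil markers (16 adjusted over the list alone, median -2.69, adjusted p = 3.26e-10, and adjusted p = 0.123 with an estimated correlation). Csf3r was at -2.34 ± 0.51. It was past the threshold and negative in 10 of 17 hypoxia and glycolysis genes, and positive in 1 (12 down and 1 up adjusted over the list alone, median -0.96, adjusted p = 2.37e-09, and adjusted p = 0.0752 with an estimated correlation). Eno1 was at -1.49 ± 0.23. It was past the threshold and negative in 9 of 22 matrix genes, and positive in 1 (9 down and 1 up adjusted over the list alone, median -0.40, adjusted p = 3.6e-05, and adjusted p = 0.0671 with an estimated correlation). Spp1 was at -3.36 ± 0.42 and Col1a1 at -1.64 ± 0.26. It was past the threshold and positive in 5 of 18 alveolar macrophage markers (10 adjusted over the list alone, median 0.78, adjusted p = 3.97e-07, and adjusted p = 0.0752 with an estimated correlation). Ear2 was at 1.56 ± 0.20. Without the 3 libraries that stand apart the count was 621.

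From day 2 to day 4 the responses differed in 502 genes, 156 up and 346 down. Sex changes between these days too, so the same limit holds. Without wild-type library 3 of day 4 there were 239 up and 333 down, so the balance of directions depends on that library. The difference was past the threshold and negative in 23 of 26 cell cycle genes (25 adjusted over the list alone, median -1.88, adjusted p = 3.5e-25, and adjusted p = 0.00426 with an estimated correlation). Mcm5 was at -1.90 ± 0.29, Tyms at -1.75 ± 0.28 and Rrm2 at -1.96 ± 0.33. Arg1 was at -3.73 ± 0.90, from 7869 to 12043 counts in wild type and from 3741 to 322 in the knockout, and Ska3, a spindle protein gene, at -3.74 ± 0.81. The difference was past the threshold and positive in 4 of 18 alveolar macrophage markers (6 adjusted over the list alone, median 0.60, adjusted p = 8.16e-07, and adjusted p = 0.127 with an estimated correlation). Ear1 was at 1.55 ± 0.33. It was past the threshold and positive in 3 of 16 immediate early genes (6 adjusted over the list alone, median 0.52, adjusted p = 1.21e-05, and adjusted p = 0.127 with an estimated correlation). The count was 288 without a filter on low counts, and 331, 305 and 318 without wild-type library 1 of day 2, wild-type library 4 of day 4 and knockout library 4 of day 4.

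Of the 227 list calls over the 12 comparisons 36 held with an estimated correlation. Between genotypes these were immediate early genes at day 2 and cell cycle and circadian genes at day 4. The rotation test fry kept 180. Its one-way p tests whether the genes of a set move, on balance, in one direction, its mixed p whether they change in either direction, and neither compares the set with other genes. The 39 lists (the 38 tested and the sex-linked genes) hold 636 different genes, 16 of them in more than one list: Egr1 stands in the ERK target and immediate early lists, Mmp8 and Mmp9 in the neutrophil and metalloproteinase lists, Timp1 in the matrix and metalloproteinase lists. The labels do not state in so many words that each library is a separate animal, so p-values measure the spread between these libraries, which may be technical.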

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

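Tests chosen only after the result was seen were those of clustering on chromosomes, the region around Map2k2, blood dilution, nearness to the uninfected state and an exchange of libraries. The tests of libraries that stand apart and of mixing concern libraries picked out from the data. They were therefore not fixed before the data were seen either. A library far from the others of its group was found in 4 of 102 groups over 17 quantities, and chance gives about 1 in 20. On the second principal component wild-type library 3 of day 4 was at 22.7 (others -28.9 to -19.9), its Hba-a2 was at 95.9 CPM (others 18.5 to 30.7) and its Il1rn at 493 CPM (others 115 to 136). Tyms in knockout library 3 of day 2 was at 86.0 CPM (others 61.7 to 67.2).

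Animals of day 4 were male and those of the earlier days female. In differences that use day 4, a genotype effect that differs by sex cannot be told apart from a response to infection. Changes between days differed between genotypes by a test of the difference. From day 0 to day 2 this held for 24 genes, and log2 differences among the largest were Clec3b 1.54, Trp53bp2 0.989 and Gng11 0.822, and Ifi202b -2.96, Zfp719 -2.63, Spp1 -2.57 and Inhbb -2.23. Leaving out single libraries ended 6 of these 7 calls, Spp1 being the exception, for 8 libraries (Clec3b, adjusted p = 0.0526 to 0.0693), 13 (Trp53bp2, 0.0508 to 0.0949), 6 (Gng11, 0.0514 to 0.0693), 13 (Ifi202b, 0.054 to 0.106), 5 (Zfp719, 0.0514 to 0.0693) and 8 (Inhbb, 0.0508 to 0.0693). From day 0 to day 4 it held for 1084 genes: Trim10 5.40, Neu2 5.09, Cpz 4.34, Plk5 4.24, Saa4 -12.8, Kng1 -11.2, Csf3 -9.83 and Chl1 -8.03. Saa4, Kng1, Csf3 and Chl1 each had a group at 0 counts and Plk5 a group at 3, so these are fitted values and not measured sizes: the counts over wild type day 0, knockout day 0, wild type day 4 and knockout day 4 were 0, 25, 158 and 0 (Saa4), 1, 125, 31 and 0 (Kng1), 0, 4, 83 and 0 (Csf3), 0, 30, 387 and 54 (Chl1) and 88, 74, 3 and 45 (Plk5). Knockout library 3 of day 0 held all 25 Saa4 counts and 119 Kng1 counts, and library 4 all 4 Csf3 counts. Without library 3 the adjusted p was 1 for Saa4 and 0.0911 for Kng1, and without library 4 it was 1 for Csf3. The Kng1 call also ended without wild-type library 1 of day 4 (0.0837). The Trim10 call ended without wild-type library 1 of day 0 (0.0698) or knockout library 3 of day 4 (0.0556), the Neu2 call without any one of 4 libraries (0.05 to 0.0678) and the Plk5 call without any one of 14 (0.0582 to 0.0851). The Chl1 call ended with voom (0.0565) and without the 3 libraries that stand apart (0.0793). Over all alternatives the highest adjusted p was 0.118 for Ifi202b, 0.135 for Neu2, 0.144 for Plk5 and 0.341 for Kng1. From day 2 to day 4 it held for 502 genes: Slc5a12 10.3, Fbxo40 7.62, Pck1 5.61, Tmem35a 4.78, Retnlb -5.68, Pole -4.04, Ska3 -3.74 and Arg1 -3.73. Slc5a12 had 13, 0, 0 and 31 counts over wild type day 2, knockout day 2, wild type day 4 and knockout day 4, Fbxo40 15, 0, 2 and 15, and Retnlb 81, 87, 111 and 1, so these 3 are fitted values too. The Fbxo40 call ended without any one of 10 libraries (0.0522 to 0.0856) and with voom (0.362), and the Tmem35a call without any one of 10 (0.051 to 0.108). The Pck1 call ended without knockout library 5 of day 4 (0.0794), the Pole call without wild-type library 1 of day 4 (0.065) and the Slc5a12 call with voom (0.287).

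Before infection 45 genes differed between genotypes. Of 44 autosomal genes besides Map2k2 38.6% had another called gene within 5 Mb. This equals the bound of 38.6% from 10000 random sets (median 22.7%, with 3.02% of sets at or above). A genetic background difference may or may not add to the 45 genes, and the test excludes nothing. Of 21 genes called at all 3 days 20 kept their direction, Map2k2 among them, and C1rb, C1s2 and Pianp lie close together on chromosome 6. Both go with a background difference. A lasting effect of MEK2 loss could also keep a direction, so the cause is not settled. No region carried along with Map2k2 is seen: 0 of 218 tested genes within 10 Mb were called (edgeR). Knockout libraries 3 and 4 are not the whole cause, since 64.4% of the genes were still called without them.

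At day 4 inflammatory and cell cycle genes were lower in the knockout. Wild-type library 3 is not the whole cause: 70.6% of the genes were still called without it, and 24 cell cycle genes. The inflammatory part was smaller without it: 8 instead of 14 of 26 cytokine genes and 1 instead of 3 type I interferon genes were called, the neutrophil median went from -2.26 to -1.24, and the antimicrobial list was no longer called (adjusted p = 0.0524). Dilution by blood would lower other lung cells alike, and the lowest of the medians of alveolar type 1, alveolar type 2 and endothelial markers was 0.416. CPM are shares of a library, so fewer inflammatory transcripts would by themselves raise these medians. The test therefore cannot exclude more blood in the knockout lungs, where erythroid genes were higher. Knockout lungs may be nearer to the uninfected state: 94.1% of the genes called had the sign opposite to the wild-type change from day 0 to day 2, against 72.8% of all tested genes. All tested genes include many with little change, so the higher share among called genes gives no separate support. Wild-type library 3, which lay within the day 2 range on the first principal component, was kept in. The share without it was not computed.

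Knockout library 4 of day 0 held more inflammatory transcripts than its group. Mixing with an infected library cannot be told apart from a response of the animal: for the best of 20 infected libraries 76.1% of strongly induced genes lay within the counting interval of 1 share (6.02%). An exchange with another group is excluded: its Map2k2 level of 34.9 CPM lies below every wild-type library (109 or more) and every knockout library of day 2 (73.3 or more), and it had 0 Y-linked counts where knockout libraries of day 4 had 454 to 615.

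Each count of changed genes was set against 100 splits of the same libraries, the real one among them. Outside the differences in response, a count that no other split reached is unlikely to come from a random division of these libraries alone. With 100 splits the smallest share that can be seen is 1 in 100. The splits take each library as a separate unit, which the labels do not state. Between genotypes the real counts and the highest of the other splits were 45 and 1, 934 and 258, and 2639 and 1018 at days 0, 2 and 4, with 1 split as large, the real one. For wild type they were 6580 and 2578, 5393 and 2029, and 1195 and 1874, the last with 3 splits as large. For the knockout they were 5584 and 1044, 1697 and 89, and 2890 and 95. For the differences in response they were 24 and 2, 1084 and 1118 (2 splits as large), and 502 and 1174 (3 splits as large). Their splits reshuffled genotypes within each day, which tests for no genotype effect at all and not for equal responses. These splits therefore cannot decide whether the responses differ. Why some splits called more genes than the real one was not tested.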

How the results depend on the processing

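Leaving out the 3 libraries that stand apart and thinning every library to 1 total were chosen after seeing the data. The cause of the moves below was not tested. Counts of changed genes stayed within 1.5 times with DESeq2 size factors, the stricter filter and thinning. With no filter beyond 1 count, more genes are tested, and knockout against wild type at day 2 gave 534 and the difference in response from day 2 to day 4 gave 288. The DESeq2 Wald test gave 94 at day 0 and 232 for the difference in response to day 2, and voom gave 109 and 93. A fit of the compared groups alone gave 554 at day 2 between genotypes, 466 for wild type from day 2 to day 4 and 99 for the difference in response to day 2. Against a 1.5-fold change the glmTreat counts were 18, 48 and 481 between genotypes at days 0, 2 and 4. For day 2 against 0, day 4 against 0 and day 4 against 2 they were 3060, 2135 and 209 in wild type and 2113, 302 and 429 in the knockout, and 0, 143 and 8 for the differences in response. The first of these differences had 24 genes by the test of any change. With edgeR 1837 of 14544 genes had an unadjusted p under 0.05 there, where a share of 0.05 is expected with no difference. Without the 3 libraries wild type from day 2 to day 4 gave 2034, and the differences in response to day 2 and to day 4 gave 56 and 621.

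With single libraries left out, counts ranged from 35 to 40 at day 0, 440 (without WT_day2 replicate 2) to 1031 at day 2 and 2018 to 2844 at day 4 between genotypes. At day 2 they were also 474, 612, 557 and 491 without WT_day2 replicate 3 and KO_day2 replicates 3, 4 and 5. Wild type gave 5977 to 6490, 4813 to 5441 and, from day 2 to day 4, 766 (without WT_day2 replicate 2) to 2046 (without WT_day4 replicate 3). The knockout gave 5071 to 5375, 1323 to 1606 and 2310 to 2776. The difference in response to day 2 gave 3 to 74: 6, 15, 13 and 11 without WT_day0 replicates 1, 2, 4 and 5, 14 without KO_day0 replicate 4, 59, 3, 4, 62 and 62 without WT_day2 replicates 1 to 5, and 74, 13, 3 and 8 without KO_day2 replicates 1, 3, 4 and 5. To day 4 it gave 825 to 1397, and from day 2 to day 4 305 (without WT_day4 replicate 4) to 710, with 331 and 318 without WT_day2 replicate 1 and KO_day4 replicate 4. Ngp turned direction between genotypes at day 4 with voom (0.121), without the 3 libraries (0.215) and without WT_day4 replicate 3 (0.2), with single libraries out from -2.71 to 0.2. In wild type from day 0 to day 4 it turned without the 3 libraries (-0.055) and without WT_day4 replicate 3 (-0.0577), with single libraries out up to 2.78.

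Of 227 list calls 36 were kept with an estimated correlation and 180 with fry. The replicate block moved no count of genes by more than 1.5 times. Over 75 pairs with the same number the correlation of deviations was -0.071 to 0.13, mean 0.0032, and 5 of 30 libraries correlated best with their own number, so the numbers were not treated as pairing. The lowest total was 2411418 counts, and whether deeper sequencing would call more genes was not tested.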

Other observations

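All values here were looked up after the data were seen. Knockout library 3 of day 0 held 1694 counts of Bpifa1, and the next highest library of its group 226. Knockout library 4 of day 0 held 1366 counts of Lcn2, and the next highest of its group 677. Of the 45 genes called at day 0, 8 lie on chromosome 6 (2.46 expected from the genes tested there) and 7 on chromosome 5 (2.89 expected). Of the 21 genes called at all 3 days 12 are protein coding.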
